A study of Caenorhabditis elegans with 2 samples.

How the data were processed

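Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole L4 larvae, the last larval stage of Caenorhabditis elegans, of a strain that carries an integrated transgene with eGFP-tagged snpc-4 on an unc-119 mutant background, per the labels. SNPC-4 is the worm relative of a subunit of the small nuclear RNA-activating protein complex (SNAPc), which binds promoters of small nuclear RNA genes. Both samples form 1 group and are biological replicates, numbered 1 and 2 per the labels. No untagged or input sample was analysed here, so background was not measured in a control. Per the deposited file records, each replicate list was made from that replicate's alignments and a further file shared by both replicates, whose content is not given in the sources used here; the labels name a possible control experiment.

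The files used are peak lists in the 10-column narrowPeak format. For each peak the authors deposited a signal value, a −log10 of the q-value and a summit position; the column for p holds no values. Per the labels, the lists were made against the ce10 and ce11 builds. The aligner, the peak caller and the irreproducible discovery rate (IDR) threshold are not given in the sources used here. The scale of the signal is not stated either, so it was used only to rank, filter or describe peaks within a list. The −log10 (q-value) deposited by the authors is tied at 3.16 for all 381 IDR peaks and was not used to rank them.

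The main list holds the 381 peaks of the authors' optimal IDR-thresholded list (ce11), made from both replicates. Whether each peak passed between the 2 replicates is not stated. The word reproducible is used below as a name for this list. Of its peaks, 365 had a summit within 200 bp in both replicate lists. All 381 were identical in interval and signal to the 381 strongest of 30000 peaks in the list the authors made from the pooled replicates. The replicate lists hold 11042 and 30000 peaks for replicates 1 and 2, at no stated threshold. Equal numbers of their strongest peaks were used for replicate overlap and for each replicate alone; the share of reproducible peaks found in each list, the signal within a list and the ranks at snpc-4 and unc-119 use the full lists, so they are not matched in length. The read depth of each sample is unknown, since the files give no read counts; no depth-based interval or floor was computed, and intervals on shares cover the counting of peaks or genes only. With 1 group of 2 samples there was no comparison between groups and no test over samples. The p-values below are over genome positions, peaks or genes within these lists, not over animals.

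Genes came from the Ensembl 115 annotation of WBcel235, which has the sequence of ce11; RefSeq records of the same assembly added gene names and tRNA types by WormBase identifier. The genome sequence was that of RefSeq. The mitochondrial genome was left out. A peak was assigned to every gene class with a 5′ end within 300 bp of its summit. The 25 gene classes and lists, the tests of the report, most alternative settings and the rule for named genes were chosen before the data were examined; settings and tests added later are named as such beside the additional observations. The peaks at each class were compared with 100000 circular shifts of the summits within each chromosome (2-sided, 2 times the smaller tail). The share of genes with a peak was compared with protein-coding genes outside the list by 2-sided Fisher's exact test, with Clopper-Pearson 95% intervals. Signal was compared as rank percentile within a list by permuting class labels 100000 times, against peaks at protein-coding genes with no small RNA gene. Summit positions were given 10000-draw bootstrap intervals and an exact sign test. Replicate overlap counted summits within 200 bp among equal numbers of peaks, against 1000 circular shifts. Families of p-values were adjusted by Benjamini-Hochberg.

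Sequence within 100 bp of each summit was compared with windows centred 1000 bp to either side. The core of the motif found upstream of 21U-RNA genes, CTGTTTCA, was tested by the exact McNemar test, and 8-mers were searched among 191 odd-ranked peaks and tested on the 190 even-ranked ones by Fisher's exact test. A summit sequence had a second copy if blastn found at least 90% identity over at least 80% of its length elsewhere; this definition was set after the files were in hand and before the search was run. The text names the closest gene within 1 kb of each of the 20 strongest peaks, up to 3 genes of highest signal per list, and for 5 lists of special interest (RNase P, RNase MRP and Y RNA, SmY RNA, SNAPc and RNA polymerase III, the piRNA pathway, the transgene) every gene with a peak and the first 3 without. Genes of 1 list sharing a peak are named together; genes of other lists at the same peak are named in some cases only. The genes W05B2.8, F38E11.10 and C52E4.8 go by their RefSeq names, since their Ensembl names belong to other snRNA loci.

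The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and blastn 2.17.0. It was tested on simulated data: of 381 simulated summits, 40 were planted at snoRNA genes 50 bp upstream of the 5′ end, 41 were then counted there at a median of −50 bp, and 0 of the other classes were called. In 40 uniform sets, 6.95% of 187 class tests with at least 3 expected peaks had p under 0.05, 0% of the tests of the chromosome IV regions did, and 7.5% of the signal permutation tests on unchanged values did. With an 8-mer placed in 22.3% of simulated windows, 5 8-mers were called, the planted one among them, and 0 were called without it. Alternatives covered the window, the threshold, each replicate alone, repeated sequence, counting rules and matching distance; the ce10 list was used for its peak number only.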

Results

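The sites bound by eGFP-tagged SNPC-4 in L4 larvae were mapped by ChIP-seq in 2 biological replicates. The question the design addresses is which promoters the protein occupies and how far the replicates share them. There was 1 group and no control sample among those analysed. The reproducible list held 381 peaks on ce11, with a median signal of 31.7 and a range of 21.4 to 1230, so a small number of peaks stood far above the rest.

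The strongest peaks lay at genes of small non-coding RNAs. The highest (signal 1230; 579 in replicate 1 and 651 in replicate 2) had its summit at chromosome II position 15025975, upstream of the snoRNA gene Y53F4B.47 (WBGene00045141; 15025814 to 15025893) and of cmtr-1, which encodes an mRNA cap methyltransferase. Next came the snRNA gene W05B2.8 (WBGene00014543, under the name R07E5.16 in the Ensembl file, which gives that name to several snRNA genes; chromosome III, 10989679 to 10989780; signal 1112), inside an intron of a protein-coding gene, and the unclassified non-coding RNA gene F08G2.13 (WBGene00045119; chromosome II, 13834449 to 13834523; signal 1005), outside protein-coding genes. The rest of the 20 strongest peaks lay closest to ZK994.7, sls-2.8, sls-2.4, Y37E3.29 with the snoRNA gene Y37E3.20, sls-2.2, rpr-1, F01D5.12, sls-2.1, W01D2.7, F38E11.10 (WBGene00014366), C52E4.8 (WBGene00014291), F58G1.11 with the snRNA gene sup-6, mir-2214, Y55F3BR.9, C16D9.11, F54D8.7 and F32B5.9. Of the 100 strongest peaks, 72 were within 300 bp of the 5′ end of a small RNA gene (72%, 95% interval 62.1 to 80.5), against 23 of the next 100 (23%, 15.2 to 32.5) and 33 of the last 181 (18.2%, 12.9 to 24.6). Small RNA here means snRNA, spliced leader, SmY, RNase P, RNase MRP, Y RNA, tRNA, snoRNA, miRNA and rRNA genes.

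The SL2, SmY and snRNA genes had more peaks than chance. SL2 RNAs donate the leader added to the downstream genes of operons: 14 of the 19 SL2 genes had a peak (73.7%, 48.8 to 90.9), among them sls-2.8 (912), sls-2.4 (892) and sls-2.2 (766). Genes of the snRNA biotype, with spliced leader and SmY genes taken out, had a peak in 28 of 89 cases (31.5%, 22 to 42.2). In front were W05B2.8, F38E11.10 (559) and C52E4.8 (549). The count includes mir-1831, which lies inside sup-39 and shares its peak. SmY RNAs, which take part in trans-splicing, had a peak at 3 of 12 genes: smy-2 (427), smy-3 (178) and smy-8 (31.4). The genes smy-1, smy-10 and smy-11 had none, and smy-8 had no summit within 300 bp among the 381 strongest of replicate 2. Against protein-coding genes, of which 132 of 19973 had a peak (0.661%, 0.553 to 0.783), the excess gave adjusted p = 5.84e-26 for SL2, 2.54e-36 for snRNA and 0.000152 for SmY by Fisher's exact test. By circular-shift permutation the peaks numbered 15 at SL2 genes against 0.043 expected and 30 at snRNA genes against 0.188 expected (both adjusted p = 7.14e-05, from raw p = 2e-05, the smallest the shifts can give), and 3 at SmY genes against 0.0251 (adjusted p = 0.000444). The excess over the shifts was smaller within 1000 bp, at 117-fold for SL2, 51.7-fold for snRNA and 47.6-fold for SmY genes, and larger within 150 bp, at 607-fold, 292-fold and 225-fold.

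The genes of all 3 RNAs of RNase P (rpr-1, signal 759), RNase MRP (mrpr-1, 422) and the Y RNA (yrn-1, 30.4) had a peak; these RNAs act in tRNA processing, rRNA processing and Ro particles. Adjusted p was 9.06e-07 by Fisher's exact test and 0.000125 by circular-shift permutation. The summit of rpr-1 lay on chromosome I at 13463928, at −27 bp from the 5′ end of the gene (13463955 to 13464207). At mrpr-1 (chromosome II, 7200233 to 7200418) it lay at −26 bp, and at yrn-1 (chromosome IV, 7499508 to 7499612), which had no summit within 300 bp among the 381 strongest of replicate 2, at −14 bp.

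Among snoRNA genes, whose RNAs guide the modification of rRNA, 39 of 344 had a peak (11.3%, 8.19 to 15.2; adjusted p = 8.48e-32, Fisher's exact test). The strongest were at Y53F4B.47, ZK994.7 (928) and Y37E3.20 (835). For tRNA genes the share was 37 of 612 (6.05%, 4.29 to 8.24; adjusted p = 4.73e-21, Fisher's exact test). The highest were C27A2.t1, a tRNA-Ile gene (351), K11H12.t1, the single annotated tRNA-Sec gene, for selenocysteine (295), and M01E5.t1, a tRNA-Lys gene whose peak it shares with sls-2.9 (275). In circular-shift permutation, 40 peaks at snoRNA genes compared with 0.771 expected and 34 at tRNA genes with 1.33 (both adjusted p = 7.14e-05). Of 261 miRNA genes, 4 had a peak, led by mir-2214 (535), cel-mir-8196a (129) and cel-mir-8196b (35.2). That number passed the shift permutation (0.551 expected, adjusted p = 0.0144) but not Fisher's exact test against protein-coding genes (adjusted p = 0.199). It also did not pass with the 381 strongest peaks of replicate 1 alone (3 peaks, adjusted p = 0.0871, permutation) or within 1000 bp (adjusted p = 0.0543, permutation).

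The SL1 genes, which lie with the 5S rRNA genes in a repeated array, had 0 peaks in 12 genes (upper 95% bound 26.5%), and the 20 rRNA genes also had 0 (upper bound 16.8%). How the authors treated reads from repeated genes is not given in the sources used here, so absence from the list is not a measure of binding there.

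**Figure D1:**
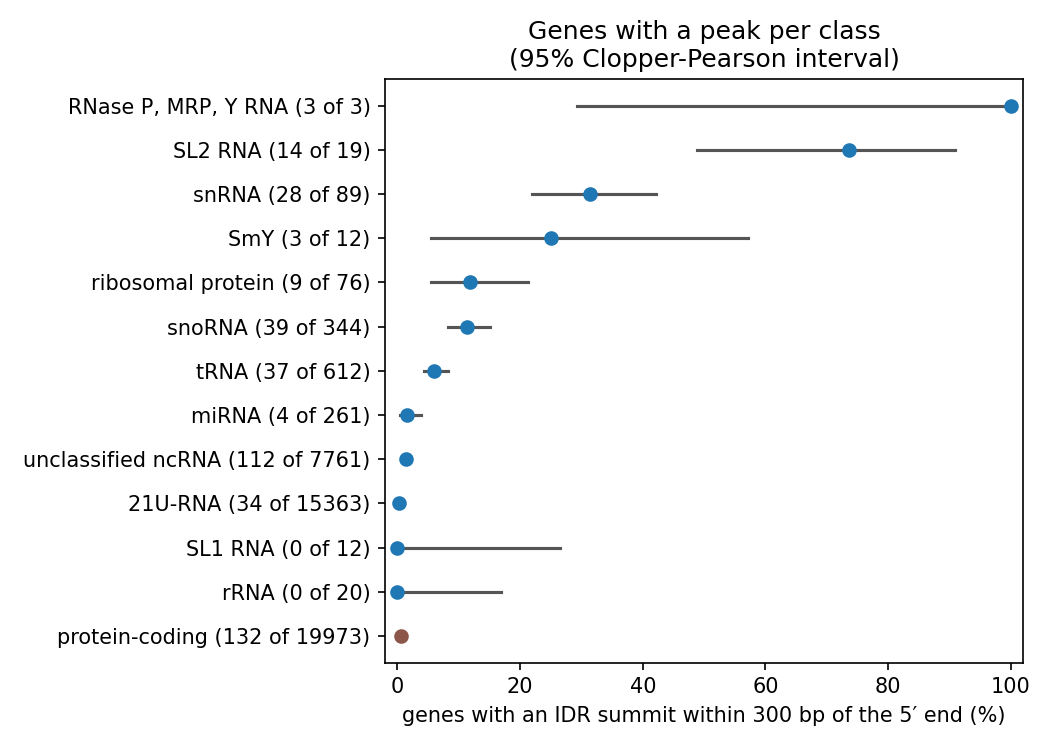
Share of genes of each class with a reproducible peak summit within 300 bp of the 5′ end (points, in percent) with the Clopper-Pearson 95% interval (lines); numbers of genes are in the labels. SL2 (73.7%) and snRNA genes (31.5%) lie far above protein-coding genes (0.661%), while 21U-RNA genes (0.221%) lie below them.

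Peaks at protein-coding genes were more frequent than chance and weak. Their 5′ ends had 105 peaks against 43.7 expected (fold 2.40, adjusted p = 7.14e-05, circular-shift permutation), of which 92 had no small RNA gene nearby. The strongest peaks with a protein-coding 5′ end, at cmtr-1, tim-1 and Y75B8A.23, were those of Y53F4B.47 and sls-2.8. Ribosomal protein genes stood out: 9 of 76 had a peak (11.8%, 5.56 to 21.3; adjusted p = 7.16e-09, Fisher's exact test; 0.169 peaks expected by shift permutation, adjusted p = 7.14e-05), led by rpl-3 (48.0), rps-19 (37.3; a peak shared with hsr-9) and rps-12 (35; shared with the snoRNA gene F54E7.10 and ska-3). Without peaks at small RNA genes 8 of the 76 had a peak (adjusted p = 9.63e-08, Fisher's exact test). Within 1000 bp 18 of the 76 had a peak (23.7%; adjusted p = 4.10e-17, Fisher's exact test), but the call was lost within 150 bp, where 1 did (adjusted p = 0.327, Fisher's exact test), and when peaks had to overlap the gene body, where also 1 did (adjusted p = 1, Fisher's exact test). Among the 381 strongest peaks of replicate 2 rps-19 had no summit within 300 bp. Its reproducible peak did have a match there, at rank 192, with a summit within 200 bp of its own. Of 72 histone genes, 1 (his-37, 32.8) had a peak, which did not pass the test (adjusted p = 0.406, shift permutation); in the 381 strongest peaks of replicate 1 alone there were 2 peaks (adjusted p = 0.0496, permutation). The 14 SNAPc and RNA polymerase III genes (snpc-1.1, snpc-1.2 and snpc-1.3 among them), the 17 piRNA pathway genes found in the annotation (prg-1, prg-2 and prde-1 among them), 7 Sm protein genes and the muscle, collagen, intestinal and germline lists of 10, 159, 10 and 14 genes had 0 peaks, with adjusted p = 1 in both the exact and the permutation test. The chemoreceptor list had 0 peaks in 1356 genes, below the other protein-coding genes by Fisher's exact test (adjusted p = 0.000363) and with 2.70 expected by shift permutation (adjusted p = 0.268). The first call was lost within 150 bp (adjusted p = 0.116, exact) and in the upper 50% of peaks (adjusted p = 0.0970, exact).

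Other non-coding classes differed. Unclassified non-coding RNA genes had 97 peaks against 14.9 expected (fold 6.52, adjusted p = 7.14e-05, circular-shift permutation). With each peak counted for a single class 28 were left (fold 2.37, adjusted p = 0.000210, permutation), and within 1000 bp the fold was 2.86 (adjusted p = 7.14e-05, permutation). The highest were F08G2.13, Y75B8A.49 and R12E2.18, and the last 2 lie antisense to sls-2.8 and sls-2.4 and share their peaks. Long non-coding RNA genes (anr-36, linc-108 and linc-54) had 3 peaks against 0.675 expected (adjusted p = 0.153, permutation; 5 peaks and adjusted p = 0.00360 in replicate 2 alone; linc-108 and linc-54 had none among the 381 strongest of replicate 1), and pseudogenes had 1 (Y17D7C.3) against 4.60 (adjusted p = 0.247, permutation; adjusted p = 0.000112 for the lower share of genes, Fisher's exact test, and 0.128 within 150 bp). With replicate 1 alone pseudogenes had 2 peaks (fold 0.419 instead of 0.217). No annotated 5′ end of any class lay within 300 bp of 123 of the 381 peaks (32.3%, 27.6 to 37.2).

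SNPC-4 has been linked to 21U-RNAs, the piRNAs of nematodes, whose genes lie mainly on chromosome IV. At 21U-RNA 5′ ends there were 17 peaks against 15.7 expected (fold 1.08, adjusted p = 1, circular-shift permutation). Within 150 bp the fold was 0.734 (adjusted p = 1, permutation). Among 15363 such genes, 34 had a peak (0.221%, 0.153 to 0.309), a lower share than among protein-coding genes (adjusted p = 3.49e-09, Fisher's exact test). These genes are clustered and share peaks, so that p is too small. With 5′ ends within 300 bp merged, 18 of 5741 had a peak (0.314%, adjusted p = 0.00953, Fisher's exact test). The strongest peaks near 21U-RNA genes were those of 21ur-7591 with 21ur-10179 (188) and of 21ur-14704 (184). Their summits lay at 221, 224 and −268 bp from the 5′ ends. The first peak is also that of the snoRNA gene Y67A10A.14, the second also that of the snRNA gene sup-39. The 21U-RNA regions of chromosome IV held 39 of the 70 peaks on that chromosome against 24.7 expected (fold 1.58, p = 0.0770, circular-shift permutation within the chromosome), and 20 of these 39 had no small RNA gene nearby. With the 381 strongest peaks of replicate 1 alone the fold was 1.80 (p = 0.0386, permutation), and with those of replicate 2 alone it was 1.32 (p = 0.360, permutation). The difference between these folds was not tested. The core motif CTGTTTCA occurred at 2 of 381 summits (0.525%, 0.0636 to 1.88), with 4 and 7 in the left and right flanks (exact McNemar p = 0.688 and 0.125). Chromosome IV as a whole held 18.4% of the peaks and 17.4% of the genome (p = 0.637, exact binomial test). It held 23.4% of the 381 strongest peaks of replicate 1 (p = 0.00360, exact binomial test) and 15.7% of those of replicate 2 (p = 0.418, exact binomial test).

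Peaks at small RNA genes were stronger than those at protein-coding genes with no small RNA gene nearby, whose median signal was 27.8 (87 peaks found in both replicates). Median signal was 191 at SL2 genes, 179 at snoRNA genes and 83.3 at snRNA genes. The rank percentile was higher for each (adjusted p = 9e-05, permutation, from raw p = 1e-05, the smallest the draws can give). The same held within replicate 1 (adjusted p = 0.0204, 0.000594 and 0.00428 for SL2, snoRNA and snRNA, permutation) and within replicate 2 (adjusted p = 0.0361, 0.000135 and 0.0135, permutation). In replicate 2, without peaks of repeated sequence, the SL2 difference was 0.707 percentile points for 13 peaks instead of 0.687 for 15, no longer past the threshold (adjusted p = 0.0585, permutation). At tRNA genes the median signal was 32 and did not differ from protein-coding peaks (adjusted p = 0.307, permutation).

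**Figure D2:**
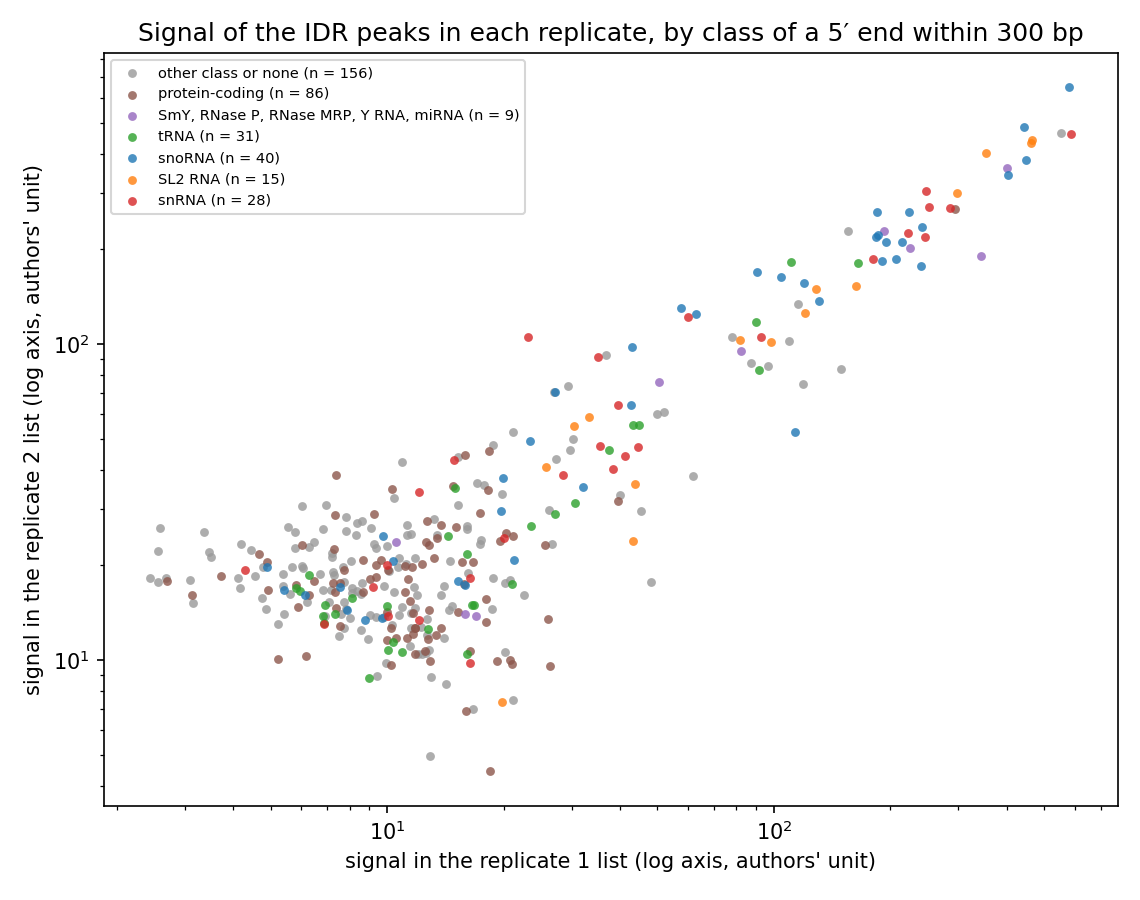
Signal of each reproducible peak in the replicate 1 list (x axis) and the replicate 2 list (y axis), both on log axes in the authors' unit; each point is a peak found in both lists, coloured by the class of a 5′ end within 300 bp. Peaks at snRNA, SL2 and snoRNA genes make up most of the upper right, where both replicates rank the peaks alike, and most protein-coding peaks lie in the dense lower left.

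Summits lay mostly upstream of snRNA, SL2 and snoRNA genes and close to the 5′ end. The median was −53.5 bp at snRNA genes (95% interval −58 to −44; 25 of 30 upstream, adjusted p = 0.00108, exact sign test), −48 bp at SL2 genes (−52 to −39; 13 of 15, adjusted p = 0.0148, exact sign test) and −44 bp at snoRNA genes (−53 to −33.5; 37 of 40, adjusted p = 9.73e-08, exact sign test). Summits at tRNA genes lay closer to the 5′ end, at −15.5 bp (−18 to −3; 23 of 34 upstream, adjusted p = 0.0960, exact sign test), and at −9.5 bp with the 381 strongest peaks of replicate 1 alone. At protein-coding genes they lay farther away, at −160 bp (−182 to −138; 95 of 105, adjusted p = 1.59e-17, exact sign test). At unclassified non-coding RNA genes most lay downstream of the 5′ end (median 85 bp, 37 to 100, with 65 of 97 downstream, adjusted p = 0.00262, exact sign test). Many of these peaks are shared with another class, and 28 were left with each peak counted for a single class. The summits at Y75B8A.49 and R12E2.18 (163 and 148 bp) are those upstream of sls-2.8 and sls-2.4. The median therefore does not describe unclassified genes alone, and the position at the 28 was not tested. Near 21U-RNA genes neither side was preferred (median −18 bp; 9 upstream, 8 downstream; adjusted p = 1, exact sign test). Only 21 of the 381 summits fell in a protein-coding exon (5.51%, 3.44 to 8.30, where exons make up 29.5% of the genome), 125 fell in an intron and the rest outside protein-coding genes.

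**Figure D3:**
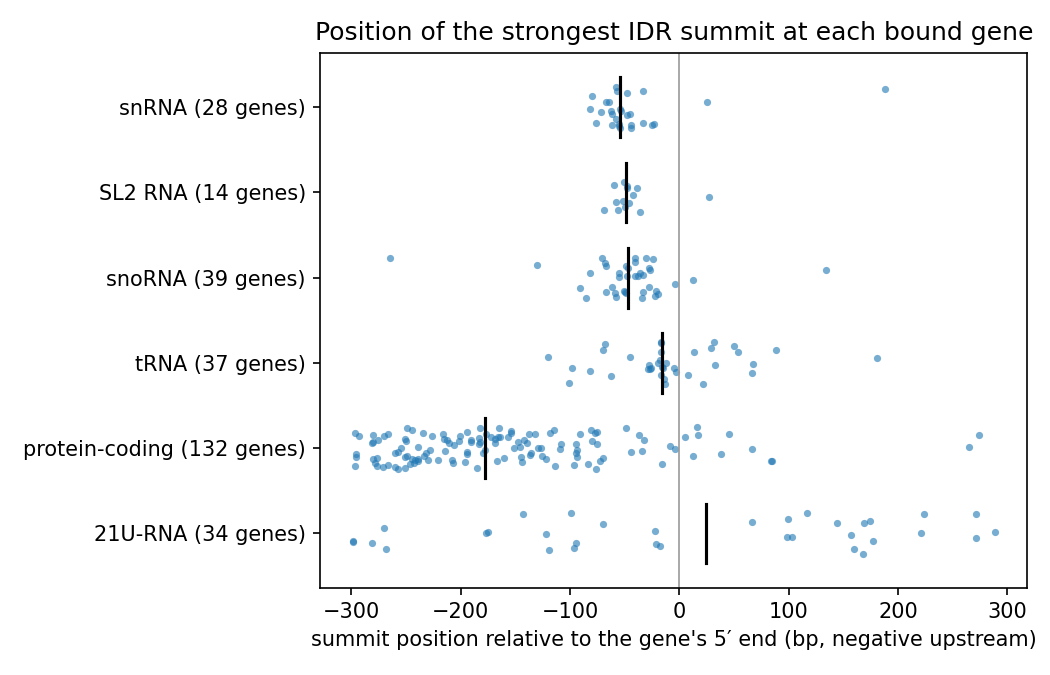
Position of the strongest summit relative to the 5′ end of each gene with a peak (x axis in bp, negative upstream), by class; each point is a gene and the black bar the median over genes. Medians are −54.5 bp for snRNA, −49 bp for SL2, −47 bp for snoRNA, −16 bp for tRNA and −177.5 bp for protein-coding genes; 21U-RNA genes scatter on both sides.

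Shared sequence marked the peaks. Of 28133 8-mers present, 38 were found in odd-ranked peaks and 32 of these passed in the even-ranked ones. The top 8-mer GCGGAACC occurred in 35 of 190 even-ranked peaks (18.4%) and 0.789% of flanks (adjusted p = 2.44e-13, Fisher's exact test), and GGCCGACA in 25 (13.2%; adjusted p = 2.14e-09, Fisher's exact test). At least 1 of the 32 was present at 112 of the 190 even-ranked summits (58.9%, 51.6 to 66.0) and in 10% of flanks. This included 44 of 64 peaks at small RNA genes (68.8%, 55.9 to 79.8, left and right flanks 6 and 5). It also included 20 of 40 at protein-coding genes only (95% interval 33.8% to 66.2%, flanks 3 and 9). Here and below, only means with no small RNA gene within 300 bp. Such a peak can also lie at an unclassified non-coding RNA gene, as the one at W01D2.7 does. The 32 were chosen for passing on these same even-ranked peaks, so these shares are upper estimates. The 20 of 40 need not carry the sequence of small RNA genes. The 8-mers enriched at small RNA peaks were at 12 of all 92 peaks at protein-coding genes only. In the left and right flanks of the 92 they were at 4 and 9 (exact McNemar p = 0.0768 and 0.629).

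The replicates shared a part of their strongest peaks that fell as more peaks were taken, and ranked peaks at small RNA genes more alike than the others. Of the 381 strongest peaks of replicate 1, 199 had a summit within 200 bp among the 381 strongest of replicate 2 (52.2%, 47.1 to 57.3; 0.574 by circular shift, permutation p = 0.000999, the smallest the shifts can give); of the 190 strongest, 133 did (95% interval 62.9% to 76.4%). Of the 762 strongest of replicate 1, 312 had one among the 762 strongest of replicate 2 (40.9%, 37.4 to 44.5). Of the reproducible peaks, 262 (68.8%) had a match among the 381 strongest of replicate 1 and 293 (76.9%) among those of replicate 2. Nearly all were in the full replicate lists, which differ in length, 367 in replicate 1 (96.3%, 93.9 to 98.0) and 379 in replicate 2 (99.5%, 98.1 to 99.9). Across the 365 peaks in both, which are not independent replicates, signal had a Spearman rho of 0.574; across the 123 at small RNA genes it was 0.923, and across the other 242 it was 0.201. Choosing peaks by pooled signal lowers rho among weak peaks by itself, and in the lower 50% of the list it was −0.604. These values therefore do not show how far the replicates differ in ranking weak peaks.

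At snpc-4, carried on the transgene, and unc-119, mutated in the strain, no reproducible peak was found. The best peak within 2 kb of snpc-4 (chromosome I, 8962322 to 8966129) ranked 383 in the pooled list (signal 21.3), just outside the 381, and ranked 286 in replicate 1 and 430 in replicate 2. At unc-119 (chromosome III, 10902641 to 10908935), the best ranked 7586 in the pooled list, 8246 in replicate 1 and 6057 in replicate 2.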

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

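The comparison of weaker peaks and the test of extra copies, at snpc-4 and unc-119, were chosen only after the result was seen; the rearrangement test was added once the motif's excess was known. Most of the peaks below rank after the 381 strongest of their list.

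Replicate 1 placed many of its weaker peaks in the 21U-RNA regions of chromosome IV, and replicate 2 did not. At ranks 382 to 11042 of each list, 1387 peaks of replicate 1 (13%, 95% interval 12.4 to 13.7) lay in the regions. In replicate 2 there were 582 (5.46%, 5.04 to 5.91). The regions are 6.18% of the genome. The difference of the counts gave p = 0.0103 by circular-shift permutation within chromosome IV. The shifts keep the number of peaks on that chromosome, 2511 in replicate 1 and 1718 in replicate 2. That p therefore concerns placement within chromosome IV, not the difference between the shares of all peaks. The replicate 1 peaks are more AT-rich (median GC 37.8% outside chromosome IV, against 41.3%), but matching on GC left the ratio of the shares at 2.09 (bootstrap interval 1.58 to 2.71; 2.38 unmatched), so GC content is not the whole cause although it may account for part. The motif CTGTTTCA was at 21.8% of replicate 1 summits in the regions and at 16.4% and 18% of their flanks (larger exact McNemar p = 0.00829). Of the 840 rearrangements of its letters 1, the motif itself, had so large an excess (0.119%). The excess was 4.65 percentage points, and the next largest was 3.93. An excess in points can be larger for a sequence that is frequent in the flanks too. The rearrangements therefore do not decide whether base composition is the cause. Replicate 2 summits carried the motif less often than their flanks (6.36% against 12.7% and 12.5%). Median GC in the regions was 32.3% in replicate 1 and 40.3% in replicate 2, so composition at the summits may play a part. Of the replicate 1 peaks in the regions, 68.1% lay within 300 bp of a 21U-RNA 5′ end. After a move by 1000 bp left or right, 65.0% and 64.5% did (exact McNemar p = 0.0085 and 0.0026). In replicate 2 the share was 38.5%, against 47.4% and 45.5%. Weak binding at 21U-RNA genes seen in replicate 1 alone stays a hypothesis. No biological difference between the samples was tested, since the labels name none.

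Weak peaks crowd the snpc-4 locus. Within 15 kb of its 5′ end, the 11042 strongest peaks of replicate 1 included 16 and those of replicate 2 also 16, against a median of 3 in 2750 autosomal windows of 30 kb. With 500 bp to either side of the 5′ end left out, 13 remained in each, and at most 0.836% of windows had as many. Around unc-119 there were 3 and 4 peaks, as in many windows (55.7% and 40.04% of them had as many or more). Extra copies of snpc-4 on the transgene may raise the signal there, but this stays open, since unc-119 shows no crowding and the labels do not say which unc-119 sequence, if any, the transgene carries; no biological explanation was tested.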

How the results depend on the processing

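The alternatives that use weaker peaks, peaks in both replicate lists or peaks without a small RNA gene, chromosome IV in each replicate, and the 8-mers in each replicate were chosen only after the data were seen. The excess at snRNA, SL2, SmY, RNase P, MRP and Y RNA, tRNA and snoRNA genes kept its direction and stayed past the threshold in every alternative run. Their folds depend on the window: 855 and 130 for RNase P, MRP and Y RNA, 48.5 and 10.2 for tRNA, and 97.7 and 21.5 for snoRNA genes within 150 and 1000 bp. The cause was not tested for any change below.

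Within 150 bp, peaks at 21U-RNA genes were 0.734 times the shifted number and at ribosomal protein genes 11.9 times (no longer passing), and the shares of pseudogenes (0.0470%), ribosomal protein genes (1.32%) and chemoreceptor genes (0%) no longer passed. Within 1000 bp the folds were 3.41 for miRNA (no longer passing), 0.343 for pseudogenes (now passing) and 1.69 for collagens (turned). Gene-body overlap gave 1.32% of ribosomal protein genes, and the upper 50% of peaks 0% of chemoreceptor genes, neither passing; counting each peak once gave a fold of 0.512 at 21U-RNA genes; peaks in both lists gave 5.65 for miRNA, not passing. The upper 50% raised the regions of chromosome IV to 1.77 (passing), weaker peaks of replicate 1 gave 1.56 and of replicate 2 0.956. With 1 mismatch allowed the 21U motif was at 15.2% of summits, below the flanks and now passing. Without mismatches it was at 21.8% (replicate 1) and 6.36% (replicate 2) of the weaker peaks in the regions. SL2 peaks of unique sequence in replicate 2 (13 instead of 15) lay 0.707 percentile points higher, not less than the 0.687 of all, but no longer passing. Reproducible peaks in replicate 1 fell to 91.9% by reciprocal overlap and 82.9% among its 762 strongest, and in replicate 2 to 95.3% and 91.3%.

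With each replicate left out in turn, folds ranged from 0.874 to 1.18 at 21U-RNA, 2.99 to 7.46 at lncRNA, 5.55 to 7.16 at miRNA, 0.219 to 0.419 at pseudogenes and 8.38 to 15.2 at histone genes, and from 1.32 to 1.80 in the regions of chromosome IV. Shares of genes ranged from 0.680% to 1.70% for lncRNA, 1.39% to 4.17% for histones, 16.7% to 41.7% for SmY, 7.89% to 17.1% for ribosomal proteins, 0.0470% to 0.0940% for pseudogenes and 0.143% to 0.286% for 21U-RNA, peaks on chromosome IV from 15.7% to 23.4%, and the median summit at 21U-RNA genes from 44 to 49.5 bp, both turned from −18 bp. The median at tRNA genes was −11 and −9.5 bp, and the 21U motif was at 0.787% of summits in each replicate. Ranking by the q-value column was not run, as all reproducible peaks are tied there and the p column is empty. No paired analysis was possible because there is a single group. Depth is unknown, so what it limits could not be stated.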

Other observations

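The tests on repeats and on the paired sequence boxes were chosen only after the result was seen. Among the 100 strongest peaks, 24 had neither a small RNA gene nor a protein-coding 5′ end within 300 bp. Several lie beside unclassified non-coding RNA genes, with summits near the quartiles at snRNA genes (−62 to −33 bp): F08G2.13 (−33 bp), ZK265.11 (−29 bp; signal 251), C18C4.17 (−49 bp; 213), CD4.18 (−54 bp; 197), W01D2.8 (−39 bp; 171) and T19C4.16 (−54 bp; 128). Beside others of these genes the summits lay farther upstream or inside: C17G10.14 (−219 bp, signal 384), W01D2.9 (−141 bp, 148), F08G2.12 (−88 bp, 186) and M163.12 (17 bp, 66.8). The summit at W01D2.9 is a second summit in the interval of the peak at W01D2.7 (signal 588). That peak has the protein-coding 5′ end of W01D2.3 within 300 bp. The summit at W01D2.9 is among the 24 by its own position and is not a separate interval. Others of the 24 have no annotated 5′ end within 1 kb, although some of these lie inside a protein-coding gene. Examples are chromosome I position 13859253 (signal 183, intron) and chromosome III position 11463992 (signal 182, exon). These were chosen after their values were seen.

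A candidate explanation is that some of the 24 are promoters of small RNA genes missing from, or unclassified in, the annotation. The 27 8-mers enriched at annotated small RNA peaks were present at 18 of the 24 summits (75%, 53.3 to 90.2) and at 0 and 2 of their flanks (larger exact McNemar p = 3.05e-05). Across all 161 peaks with neither, 80 carried one (49.7%), against 12 of 92 at protein-coding genes only (13%). A near-identical second copy existed for 8.33% of the 24, which argues against reads shared between near-identical copies for most of them. The rule asked for 90% identity over 80% of the summit sequence, so reads shared over shorter stretches were not tested. A dispersed repeat family stays open: 41.7% of the 24 align elsewhere over at least 60 bp, about as often as their flanks (11 and 10 of 24). Of the 128 peaks at small RNA genes 70.3% did (flanks 47 and 40). At protein-coding genes only, 9 of 92 did (9.78%), fewer than their flanks (21 and 18).

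Top 8-mers overlap a pair of boxes, CGGAACC and, 5 to 9 bp further on, GTCGGC, which was in 42 of the 381 peaks. The top 8-mer GCGGAACC was in 35 odd-ranked and 35 even-ranked peaks, so it also occurs without the pair. The pair stood at 11 of the 128 peaks at small RNA genes (8.59%), with 5 of 40 at snoRNA, 2 of 30 at snRNA, 2 of 15 at SL2 and 0 of 34 at tRNA genes, at 1 of the 92 peaks at protein-coding genes only, and at 30 of the 161 peaks with neither kind of gene, 19 of them on the X chromosome. The genome holds 506 such pairs, of which 45 are within 100 bp of a reproducible summit: 21 of 122 on X (17.2%) and 24 of 384 on the autosomes (6.25%, but 17.8% on chromosome II). Near small RNA 5′ ends 11 of 18 were at a peak (61.1%, 35.7 to 82.7), and elsewhere 34 of 488 (6.97%, 4.87 to 9.60). The pattern was written from these peaks, many of them on X, so none of these shares is a test of binding or of a difference between chromosomes.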
